A study of Mus musculus with 16 samples.

How the data were processed

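Left ventricular tissue was collected from mice with a cardiomyocyte-specific knockout of Tfeb (cKO) and from control mice (WT in the labels) after sham surgery or transverse aortic constriction (TAC), an operation that narrows the aorta and loads the left ventricle with pressure. The labels give the strain as C57/BL6N and 4 biological replicates for each of the 4 groups, 16 libraries in all. RNA was extracted with TRIzol and an Aurum column kit, and libraries were made with a NEBNext Ultra RNA kit for paired-end sequencing on an Illumina instrument. Age, sex, the time after surgery and the Cre line are not stated in the labels.

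The authors deposited 1 table of raw counts per Ensembl gene ID, with 1 column per library and no normalization. The submitters' processing notes name FastQC, fastp 0.22.0, HISAT2 2.0.5, SAMtools 1.21 and featureCounts 2.0.6 with the build GRCm39. Strandedness, the annotation release and the handling of reads that map to several places are not stated, so overlapping and antisense genes could not be told apart. All values were whole numbers, and every column entered a comparison.

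The table held 57186 gene IDs, of which 51880 were matched to a symbol through a GRCm38 annotation. These carried 99.5% of all counts. At least 1 count in 1 library was present for 32327 gene IDs. Gene spans and the order of neighbouring genes came from the same GRCm38 annotation, so no coordinates are given. Totals ranged from 12946878 to 16347388 counts per library. The biological coefficient of variation over all libraries was 16.5%.

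Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 15206 tested genes, 14929 of them with a symbol. Libraries were scaled by TMM factors. A single quasi-likelihood model (robust) with 1 mean per group was fitted to all 16 libraries, leaving 12 residual degrees of freedom. The 5 comparisons were TAC against sham within each genotype, cKO against WT within each surgery, and the interaction, which is the TAC response in cKO minus that in WT. P-values from the quasi-likelihood F-test were adjusted by Benjamini-Hochberg within each comparison, and an adjusted p under 0.05 passed. Fold changes are edgeR estimates with their standard errors (SE) on the log2 scale. The SE was taken from the F statistic. Levels are CPM (counts scaled by the library total times its TMM factor), given as mean ± SD over the 4 replicates; atrial transcripts are given as CPM without TMM factors. The unadjusted counts refer to p under 0.05.

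Before the data were examined, 40 gene lists were fixed. They cover the TFEB family with the Rag-folliculin genes, lysosome, autophagy, mitochondria, fuel use, contraction, hypertrophy, ion channels, matrix, cell types, stress, immunity, growth and tissue handling. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 40 lists in each comparison. Beside each result stands the adjusted p with a correlation estimated from these libraries. The test fry gave both a directional and a mixed p. For every list the members past the threshold over all tested genes were counted, and then those past it when adjusted over the list alone. The direction printed for a list is that of camera.

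The named genes also follow a rule fixed before the data were examined. They are 12 genes named in every comparison, the 6 with the largest rise and the 6 with the largest fall in each comparison, and up to 4 members of each list with the smallest adjusted p. The largest changes were taken among genes that passed, reached a mean of 5 CPM in a compared group and showed no overlap between the libraries of both groups. Predicted genes with Gm or Rik symbols and pseudogenes were skipped. Where no list member passed, the member with the smallest p is given with its values. Other genes are named with the statement that they were chosen after their values were seen. Some genes named by the rule are not reported here.

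Single measures of 4 against 4 libraries were compared with two-sided exact permutation tests over 70 relabelings. The smallest p such a test can give is 0.0286. Each library property was tested in the 4 comparisons of 2 groups and adjusted over all of these tests.

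Alternatives planned before the data were examined were DESeq2 1.42.0 size factors, library totals only, no filter on low counts, a filter of at least 1 CPM in 4 libraries, the DESeq2 Wald test, limma voom, a fit of the compared groups alone, the replicate number as a block, leaving out mitochondrially encoded genes, thinning to the shallowest total, and leaving out each library in turn. A threshold of 0.01 was tried for the overlaps. A pair of alternatives was chosen after seeing the data, 1 without the 2 WT libraries with the most atrial transcripts and 1 with those transcripts as a covariate. The model was tested on simulated data with 200 changed genes per comparison: of genes changed 4-fold it recovered 90.9% in cKO sham against WT sham and 83.3% in the interaction, and of genes changed 1.5-fold it recovered 31.3% and 16.4%.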

Results

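Bulk RNA sequencing measured gene expression in the left ventricle of 16 mice. TFEB is a transcription factor known for driving lysosomal and autophagy genes, and the series title asks how it bears on lysosomal capacity and mitochondrial function in cardiac hypertrophy and failure. There were 4 WT sham, 4 WT TAC, 4 cKO sham and 4 cKO TAC libraries, with 12946878 to 16347388 counts each. On the first principal component, which held 42.7% of the variance, sham libraries scored from -46.98 to -2.51 and TAC libraries from 9.92 to 59.1. On the second, which held 10.2%, the WT libraries scored from 0.387 to 32.4 and the cKO libraries from -26.5 to -0.639. Mitochondrially encoded genes took 23.5% ± 2.12 of counts in WT sham, 19.8% ± 2.24 in WT TAC, 22.6% ± 1.02 in cKO sham and 17.3% ± 2.10 in cKO TAC. The fall of 5.33 points between cKO sham and cKO TAC had an exact p of 0.0286, and an adjusted p of 0.137 over the tests of library properties.

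Tfeb itself (ENSMUSG00000023990) was lower in every cKO library than in every WT library of the same surgery. Under sham it stood at 10.5 ± 1.74 CPM in cKO and 36.5 ± 3.94 CPM in WT, which is 28.7% of the WT level (log2 fold change -1.80, SE 0.20, adjusted p = 0.000604, exact p = 0.0286, n = 4). Under TAC it stood at 12.7 ± 2.34 CPM in cKO and 29.1 ± 9.77 CPM in WT, or 43.9% of the WT level (log2 -1.19, SE 0.20, adjusted p = 0.0138, exact p = 0.0286). Single libraries held 30.9, 37.4, 40.1 and 37.6 CPM in WT sham and 10.04, 9.12, 9.68 and 13.0 CPM in cKO sham; replicates 2, 3 and 4 of WT TAC held 34.6, 20.6 and 21.1 CPM, and those of cKO TAC 13.8, 13.0 and 9.37 CPM. Without WT TAC replicate 2 the TAC contrast was -1.11 with an adjusted p of 0.0645, and in a fit of the compared groups alone it was -1.19 with an adjusted p of 0.0543. TAC did not change Tfeb past the threshold in WT (log2 -0.33, SE 0.19, adjusted p = 0.256) or in cKO (0.28, SE 0.21, adjusted p = 0.341). Its paralog Tfe3 did not pass between genotypes (log2 -0.03, SE 0.10 under sham and -0.01, SE 0.10 under TAC), and neither did Mitf (-0.24, SE 0.12 and -0.35, SE 0.13).

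**Figure D1:**
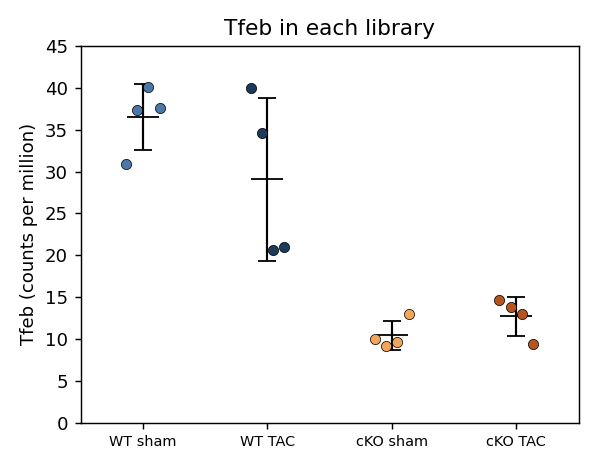
Tfeb level (CPM) in each library of the 4 groups; points are libraries, the horizontal bar is the group mean and the whiskers are 1 SD (n = 4). All cKO libraries lie between 9.12 and 14.7 CPM and all WT libraries between 20.6 and 40.1 CPM.

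The comparison of WT TAC with WT sham asks what pressure overload does to the control ventricle. Of the genes tested 54 of 64 of matrix, 30 of 34 of the cell cycle and 27 of 35 of the interferon response rose, and 24 of 36 of fatty acid oxidation and 16 of 21 of branched-chain amino acid and ketone catabolism fell. None of these 5 lists passed with an estimated correlation (adjusted p = 0.194, 0.118, 0.194, 0.230 and 0.263). Periostin (Postn), a matrix protein of activated fibroblasts, rose 8.50-fold (SE 0.49 log2) from 46.0 ± 20.5 to 391.5 ± 162 CPM (n = 4), and the collagen gene Col1a1 rose 4.09-fold (SE 0.29). The slow myosin heavy chain Myh7, a gene of the fetal heart, rose by 1.81 log2 (SE 0.28) from 351.5 ± 70.9 to 1229 ± 506 CPM. Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell to 0.676 of the sham level (SE 0.13 log2). The largest rises by the fixed rule were Igfbp2, a binding protein of insulin-like growth factors (84.2-fold, SE 1.08 log2), the secreted collagen repeat protein Cthrc1 (log2 5.30, SE 0.77), the transcription factor Etv4 (log2 3.72, SE 0.50) and the matrix glycoprotein Tnc (log2 3.71, SE 0.56). The largest falls were the vessel growth factor Angpt1 (log2 -1.78, SE 0.32), the potassium channel subunit Kcnv2 (-1.69, SE 0.38), Ano10 (-1.59, SE 0.25) and the ephrin receptor Epha4 (-1.54, SE 0.39).

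Of 64 tested genes of extracellular matrix and fibrosis, 54 rose and none fell (61 rose adjusted over the list alone; median log2 1.55, adjusted p = 2.6e-34, and adjusted p = 0.194 with an estimated correlation). Examples are the matrix binding protein Sparc (2.83-fold), Col18a1 (2.90-fold) and the procollagen peptidase Adamts2 (2.93-fold). Of 34 cell cycle genes 30 rose (adjusted over the list alone, 32 rose and 1 fell; median 2.29, adjusted p = 0.118 with an estimated correlation), such as the topoisomerase Top2a (8.24-fold), the proliferation marker Mki67 (8.48-fold) and the cyclin Ccna2 (9.50-fold). In the interferon response list 27 of 35 genes rose (30 adjusted over the list alone; median 0.79, adjusted p = 0.194 with an estimated correlation), among them Ifit1 (2.69-fold) and Isg15 (2.42-fold). The hypertrophy and fetal marker list had 17 of 22 genes that rose (18 adjusted over the list alone; median 1.14, adjusted p = 0.194 with an estimated correlation), with the actin crosslinker Actn1 at 2.19-fold and Xirp2 at 3.24-fold. The natriuretic peptide Nppb rose 4.10-fold (SE 0.43) and skeletal actin Acta1 rose 10.2-fold (SE 0.75), and a fit of the compared groups alone ended both calls, with adjusted p of 0.0522 and 0.0672. Nppa did not pass (log2 0.25, SE 1.04, adjusted p = 0.903). Without WT sham replicate 3, which held atrial transcripts, Nppa was higher in TAC by 3.33 log2 with an adjusted p of 0.00377. Macrophage and monocyte markers rose in 9 of 28 genes (14 adjusted over the list alone; median 0.59, adjusted p = 0.318 with an estimated correlation), such as Adgre1 (1.87-fold) and Ms4a7 (3.26-fold). Fibroblast markers rose in 6 of 19 genes (8 adjusted over the list alone; adjusted p = 0.454 with an estimated correlation). The inflammation list rose in 9 of 31 genes (17 adjusted over the list alone; adjusted p = 0.194 with an estimated correlation), with the chemokine Cxcl10 at 7.01-fold and the cytokine brake Socs3 at 3.05-fold. In the integrated stress response and one-carbon list 7 of 26 genes rose and 1 fell (8 and 2 adjusted over the list alone; median 0.28, adjusted p = 0.00939, and adjusted p = 0.384 with an estimated correlation).

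Among the genes of fatty acid uptake and oxidation 24 of 36 fell and none rose (27 fell adjusted over the list alone; median log2 -0.47, adjusted p = 0.230 with an estimated correlation). Malonyl-CoA decarboxylase Mlycd fell to 0.608 of the sham level, the fatty acid transporter Slc27a1 to 0.543 and the trifunctional enzyme subunit Hadha to 0.669. Branched-chain amino acid and ketone catabolism fell in 16 of 21 genes (19 adjusted over the list alone; median -0.41, adjusted p = 0.263 with an estimated correlation), with Bckdhb, a subunit of the branched-chain ketoacid dehydrogenase, at 0.590. For nuclear-encoded oxidative phosphorylation 10 of 77 genes fell (10 adjusted over the list alone; median -0.34, adjusted p = 0.454 with an estimated correlation), such as the succinate dehydrogenase subunit Sdhc at 0.725. The citric acid cycle list fell in 6 of 24 genes (20 adjusted over the list alone; median -0.32, adjusted p = 0.353 with an estimated correlation), including Idh3g at 0.704. Mitochondrial biogenesis and dynamics fell in 6 of 27 genes (6 adjusted over the list alone; median -0.26, adjusted p = 0.263 with an estimated correlation), and mitochondrially encoded subunits in 1 of 13 (none adjusted over the list alone; median -0.35, adjusted p = 0.454 with an estimated correlation). No erythrocyte marker passed (none adjusted over the list alone; median -0.82, adjusted p = 0.0184, and adjusted p = 0.465 with an estimated correlation). Cardiac ion channels fell in 9 of 25 genes (adjusted over the list alone, 1 rose and 9 fell; adjusted p = 0.246 with an estimated correlation), with the potassium channel Kcnj11 at 0.680. The contraction and calcium handling list had 7 of 31 genes that fell (adjusted over the list alone, 1 rose and 9 fell; adjusted p = 0.454 with an estimated correlation). In the lysosomal list 8 genes rose, 5 fell and 47 did not pass (11 rose and 5 fell adjusted over the list alone; median 0.07, adjusted p = 0.439), with cathepsin K (Ctsk) at 2.40-fold and the cholesterol transporter Npc1 at 0.703. Of 52 autophagy genes 3 fell and none rose (2 fell adjusted over the list alone; median -0.11, adjusted p = 0.00209, and adjusted p = 0.209 with an estimated correlation). With library totals only the median of that list was 0.02 and that of all genes 0.11. The sign of the list median thus depends on the scaling, while it lay below that of all genes under both. Pink1, a kinase of mitochondrial autophagy, fell to 0.572.

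In total 1475 genes were higher and 934 lower in WT TAC than in WT sham. With library totals only the median of all genes moved by 0.125 log2 and the split became 2170 higher and 432 lower. Without WT TAC replicate 1 the count fell to 1234.

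The comparison of cKO TAC with cKO sham asks the same of the knockout ventricle. Of 64 matrix genes 61 rose and of 34 cell cycle genes 31 rose, while 73 of 77 nuclear-encoded oxidative phosphorylation genes and 15 of 31 contraction genes fell; none of these lists passed with an estimated correlation (adjusted p = 0.215, 0.215, 0.254 and 0.228). Cthrc1 rose by 6.98 log2 (SE 0.74) to 26.9 ± 17.6 CPM in TAC (n = 4), and Postn rose 15.9-fold (SE 0.51) from 67.2 ± 44.4 to 1071 ± 405 CPM. Other large rises were C1qtnf3 (log2 5.70, SE 1.01), the collagen binding proteoglycan Fmod (5.02, SE 0.86), Col8a2 (4.50, SE 0.61) and Col12a1 (4.43, SE 0.52). Kcnv2 fell to 0.214 of the sham level (SE 0.42), the carboxylesterase Ces1d to 0.223 (SE 0.54), the desmosome-linked protein Ppl to 0.260 (SE 0.41), the opioid precursor Penk to 0.275 (SE 0.42) and the mitochondrial carrier Ucp3 to 0.294 (SE 0.36). Myh7 rose 4.29-fold (SE 0.29), Ccn2, a growth factor linked to fibrosis, rose 4.14-fold (SE 0.40), and the adult myosin Myh6 fell to 0.686 (SE 0.13).

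Of 77 nuclear-encoded oxidative phosphorylation genes 73 fell and none rose (76 fell adjusted over the list alone; median log2 -0.60, adjusted p = 3.37e-25, and adjusted p = 0.254 with an estimated correlation). The complex I subunit Ndufa10 stood at 0.642 and Sdha at 0.603 of the sham level. Mitochondrially encoded subunits fell in 8 of 13 genes (8 adjusted over the list alone; median -0.56, adjusted p = 0.338 with an estimated correlation), such as mt-Nd2 at 0.629. Mitochondrial biogenesis and dynamics fell in 14 of 27 genes (18 adjusted over the list alone; median -0.38, adjusted p = 0.215 with an estimated correlation), with the muscle regulator Perm1 at 0.603. The fatty acid list had 29 of 36 genes that fell (30 adjusted over the list alone; median -0.75, adjusted p = 0.215 with an estimated correlation), among them Cpt2 at 0.575 and Mlycd at 0.492. Citric acid cycle genes fell in 21 of 24 cases (21 adjusted over the list alone; adjusted p = 0.227 with an estimated correlation), and amino acid and ketone catabolism in 20 of 21 (20 adjusted over the list alone; adjusted p = 0.227 with an estimated correlation). Glycolysis and glucose uptake genes went both ways, with 4 that rose and 9 that fell (5 and 12 adjusted over the list alone; median -0.17, or 0.02 with library totals only; adjusted p = 0.117), including the insulin-regulated glucose transporter Slc2a4 at 0.547. Matrix genes rose in 61 of 64 cases (62 adjusted over the list alone; median 1.96, adjusted p = 0.215 with an estimated correlation), with Col16a1 at 4.05-fold. Cell cycle genes rose in 31 of 34 cases and 1 fell (31 and 1 adjusted over the list alone; adjusted p = 0.215 with an estimated correlation), such as Pbk (16.6-fold) and Prc1 (6.28-fold). Interferon genes rose in 29 of 35 cases (33 adjusted over the list alone; adjusted p = 0.227 with an estimated correlation), with Mx1 at 3.40-fold. Of 31 contraction and calcium handling genes 1 rose and 15 fell (1 and 16 adjusted over the list alone; median -0.32, adjusted p = 0.228 with an estimated correlation), and of 25 ion channel genes 1 rose and 11 fell (1 and 11 adjusted over the list alone; median -0.36, adjusted p = 0.254 with an estimated correlation). Fibroblast markers rose in 11 and fell in 2 of 19 cases (11 and 3 adjusted over the list alone; median 0.56, adjusted p = 0.429 with an estimated correlation), and macrophage and monocyte markers rose in 12 of 28 (13 adjusted over the list alone; median 0.47, adjusted p = 0.406 with an estimated correlation). The hypertrophy and fetal list had 14 of 22 genes that rose (17 rose and 1 fell adjusted over the list alone; median 1.04, adjusted p = 0.242 with an estimated correlation). The autophagy list had 11 of 52 genes that fell and none that rose (5 fell adjusted over the list alone; median -0.13, or 0.06 with library totals only; adjusted p = 0.227 with an estimated correlation), with the autophagosome protein Map1lc3b at 0.757 and Pink1 at 0.525. In the lysosomal list 13 rose, 7 fell and 40 did not pass (16 and 8 adjusted over the list alone; median 0.14, adjusted p = 0.153). Vacuolar ATPase subunits rose in 3 and fell in 3 of 18 cases (3 and 3 adjusted over the list alone; median -0.05, or 0.15 with library totals only; adjusted p = 0.485).

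In total 2154 genes were higher and 1880 lower in cKO TAC than in cKO sham. With library totals only the median of all genes moved by 0.193 log2 and the split became 4013 higher and 877 lower. Of the genes that passed in WT, 1149 also rose in cKO (209 if independent) and 645 also fell (115 if independent), with no gene called in opposite directions. Across genes, which are not independent replicates, the fold changes of both genotypes had a Pearson r of 0.782.

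The comparison of cKO sham with WT sham asks what TFEB loss does before pressure overload. Of 26 genes of the integrated stress response and one-carbon metabolism 7 rose (adjusted p = 0.0986 with an estimated correlation), while no gene of the lysosomal, autophagy or vacuolar ATPase lists passed. With TAC in WT 7 genes of the first list rose and 1 fell. Whether they are the same genes was not tested, and both comparisons use the WT sham libraries. Mthfd2, a mitochondrial enzyme of folate metabolism, rose 6.44-fold (SE 0.34 log2) from 3.65 ± 1.46 to 23.6 ± 8.74 CPM (n = 4). Asparagine synthetase Asns rose 4.51-fold (SE 0.31) and Phgdh, the first enzyme of serine synthesis, rose 4.47-fold (SE 0.33).

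In the integrated stress response and one-carbon list 7 of 26 genes rose and none fell (12 rose and 1 fell adjusted over the list alone; median log2 0.37, adjusted p = 8.97e-11, and adjusted p = 0.0986 with an estimated correlation). Further genes with large rises were Tent5b (log2 2.68, SE 0.52), the endothelin Edn3 (2.42, SE 0.42) and the metal binding protein Mt2 (2.05, SE 0.45). Large falls were the muscle chloride channel Clcn1 (log2 -2.00, SE 0.36), the regulator of glycolysis Pfkfb1 (-1.98, SE 0.38), Angpt1 (-1.78, SE 0.32) and the transcription factor Foxo6 (-1.71, SE 0.39). The transcription factor Myc rose 2.55-fold (SE 0.23), the survival factor Bcl2 1.89-fold (SE 0.15) and the p53 target Phlda3 2.12-fold (SE 0.19). Of 60 lysosomal genes none passed in edgeR, and none did adjusted over the list alone, although 42 had a positive fold change (median 0.08, camera up, adjusted p = 0.0215, and adjusted p = 0.699 with an estimated correlation). The smallest p in that list was that of the tetraspanin Cd63 (log2 0.25, SE 0.09, adjusted p = 0.180). Of 52 autophagy genes none passed, adjusted over the list alone or not (median 0.03, adjusted p = 0.498), and the smallest p was that of Atg13 (0.41, SE 0.12, adjusted p = 0.101). Of 18 vacuolar ATPase subunits none passed either way (median 0.06, adjusted p = 0.0710), with Atp6ap1 at 0.22 (SE 0.07, adjusted p = 0.139). No nuclear-encoded oxidative phosphorylation gene passed (none adjusted over the list alone; median -0.19, adjusted p = 1.34e-06, and adjusted p = 0.699 with an estimated correlation). Fatty acid genes also gave no call (none adjusted over the list alone; median -0.25, adjusted p = 0.699 with an estimated correlation). The TFEB family and Rag-folliculin list had 1 gene of 10 that fell, Tfeb (1 adjusted over the list alone; adjusted p = 0.527 with an estimated correlation). The hypertrophy and fetal list had 1 gene that rose (13 rose and 1 fell adjusted over the list alone; median 0.60, adjusted p = 0.527 with an estimated correlation). In it Nppb was 3.29-fold higher without passing (SE 0.42, adjusted p = 0.0724), and it passed without WT sham replicate 1 (log2 1.41, adjusted p = 0.0478) and without WT sham replicate 3 (2.22, adjusted p = 0.0157). Macrophage and monocyte markers gave no call over all genes (12 rose adjusted over the list alone; median 0.43, adjusted p = 0.628 with an estimated correlation). Atrial markers gave none either (1 rose and 5 fell adjusted over the list alone; median -0.66, adjusted p = 0.0505). The atrial myosin light chain Myl7, chosen after its values were seen, reached 868.7 CPM without TMM factors in WT sham replicate 3 and at most 84.7 in the other sham libraries. Erythrocyte markers had a median of -0.91 with no gene past the threshold (none adjusted over the list alone; adjusted p = 0.00833, and adjusted p = 0.699 with an estimated correlation).

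In total 94 genes were higher and 84 lower in cKO sham than in WT sham. The count fell to 59 without cKO sham replicate 4, to 79 without WT sham replicate 4, to 96 without cKO sham replicate 2 and to 114 without cKO sham replicate 1. Of 28 named genes that passed, 8 passed under every alternative, among them Tfeb, Mthfd2, Asns, Phgdh, Myc, Bcl2 and Phlda3. Leaving out WT sham replicate 4 ended the calls of Tent5b and Pfkfb1, with adjusted p of 0.0711 and 0.0608. Foxo6 lost its call without any 1 of the 8 sham libraries, and Mt2 without any of them but WT sham replicate 2 and cKO sham replicate 3. Leaving out cKO sham replicate 4 ended those of Clcn1 and Angpt1, with adjusted p of 0.0596 and 0.0652.

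The comparison of cKO TAC with WT TAC asks whether the loaded ventricle differs without TFEB. Past the threshold over all tested genes, 11 of 77 genes of nuclear-encoded oxidative phosphorylation and 14 of 36 of fatty acid oxidation fell, and 6 of 64 matrix genes rose. Many more members of these lists passed when adjusted over the list alone, as given below. None of these lists passed with an estimated correlation (adjusted p = 0.312, 0.237 and 0.387). Another split of the same 8 libraries called 586 genes against 271 for genotype, so these counts do not exclude chance. Immp2l, a subunit of a mitochondrial inner membrane peptidase, fell to 0.347 of the WT TAC level (SE 0.12 log2), with 4.36 ± 0.360 CPM in cKO TAC (n = 4, adjusted p = 3.27e-06). Clcn1 fell to 0.148 (SE 0.42) and Tmem150c to 0.334 (SE 0.24), and Mthfd2 rose 2.90-fold (SE 0.32) from 6.52 ± 0.450 to 18.9 ± 7.47 CPM. Other large rises were Tent5b (log2 2.56, SE 0.44), the skeletal troponin Tnnt3 (2.35, SE 0.52) and the potassium channel Kcnj14 (1.73, SE 0.36). Other large falls were the Wnt inhibitor Wif1 (log2 -3.02, SE 0.70), the organic cation transporter Slc22a3 (to 0.354 of the WT TAC level, SE 0.27) and the ephrin Efnb3 (log2 -1.46, SE 0.26). Without WT TAC replicate 2 only 13 genes passed; Immp2l, Tmem150c and Clcn1 were among them, and each other gene named in this comparison lost its call.

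Of 77 nuclear-encoded oxidative phosphorylation genes 11 fell and none rose (66 fell adjusted over the list alone; median log2 -0.45, adjusted p = 5.37e-34, and adjusted p = 0.312 with an estimated correlation). Cox7a1 stood at 0.533 of the WT TAC level, the ATP synthase subunit Atp5g3 at 0.658 and Ndufc2 at 0.733. The fatty acid list had 14 of 36 genes that fell (24 adjusted over the list alone; median -0.44, adjusted p = 0.237 with an estimated correlation), such as Hadh (0.562), the acyl-CoA synthetase Acsl1 (0.659) and Decr1 (0.626). Citric acid cycle genes fell in 7 of 24 cases (21 adjusted over the list alone; median -0.42, adjusted p = 0.237 with an estimated correlation), with Dlst at 0.669 and the pyruvate dehydrogenase subunit Pdhb at 0.668. Amino acid and ketone catabolism fell in 7 of 21 cases (18 adjusted over the list alone; median -0.40, adjusted p = 0.239 with an estimated correlation), with Dbt at 0.641. Without WT TAC replicate 2 none of the list members named here passed, with adjusted p of 0.0684 for Acsl1, Hadh, Decr1, Pdhb and Dbt and 0.157 for Loxl3. Mitochondrial biogenesis and dynamics fell in 2 of 27 cases (9 adjusted over the list alone; adjusted p = 0.237 with an estimated correlation), Perm1 among them at 0.648. The mitochondrially encoded subunits gave no call in edgeR (none adjusted over the list alone; median -0.28, adjusted p = 0.527 with an estimated correlation). Matrix genes rose in 6 of 64 cases (41 adjusted over the list alone; median 0.82, adjusted p = 0.387 with an estimated correlation), including the growth factor Tgfb2 (2.30-fold), Col16a1 (1.79-fold), Adamts2 (1.86-fold) and the crosslinking enzyme Loxl3 (2.70-fold). Fibroblast markers had 1 that rose, Pdgfra (1.51-fold), and 1 that fell, Wif1 (6 rose and 1 fell adjusted over the list alone; median 0.43, adjusted p = 0.461 with an estimated correlation). Macrophage and monocyte markers gave no call (none adjusted over the list alone; median 0.42, adjusted p = 8.93e-05, and adjusted p = 0.461 with an estimated correlation). The stress response and one-carbon list had 2 genes that rose, Mthfd2 and Pycr1 (6 adjusted over the list alone; median 0.34, adjusted p = 0.440 with an estimated correlation). Of 60 lysosomal genes 1 rose, the acid phosphatase Acp2 at 1.29-fold (1 adjusted over the list alone; median 0.13, camera up, adjusted p = 0.000322, and adjusted p = 0.461 with an estimated correlation). Of 52 autophagy genes none passed, adjusted over the list alone or not (median 0.01, mean 0.00, adjusted p = 0.932), nor did any of 18 vacuolar ATPase subunits (median 0.01, adjusted p = 0.832). Of 31 contraction genes 1 fell (1 rose and 10 fell adjusted over the list alone; median -0.17, adjusted p = 0.461 with an estimated correlation), and of 22 hypertrophy genes 1 rose (2 adjusted over the list alone; median 0.38, adjusted p = 0.461 with an estimated correlation). Nppa (log2 1.89, SE 1.07), Nppb (0.89, SE 0.41), Myh7 (1.10, SE 0.28), Col1a1 (0.93, SE 0.28), Postn (1.45, SE 0.46) and Ccn2 (1.59, SE 0.39) did not pass, with adjusted p from 0.0577 to 0.404. Without cKO TAC replicate 3, Myh7 (1.28), Col1a1 (1.10) and Ccn2 (1.79) passed, with adjusted p of 0.0118, 0.0265 and 0.0179, and without WT TAC replicate 1 they passed with 0.0104, 0.0378 and 0.0447.

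In total 91 genes were higher and 180 lower in cKO TAC than in WT TAC, and 116 higher and 118 lower with library totals only. Single libraries moved this count far: it fell to 13 without WT TAC replicate 2, to 20 without WT TAC replicate 3, to 28, 20 and 39 without cKO TAC replicates 1, 2 and 4, and rose to 522 without WT TAC replicate 1 and 912 without cKO TAC replicate 3. Of 41 named genes that passed, Clcn1, Tmem150c and Immp2l passed under every alternative, and the other 38 lost their call under at least 1.

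**Figure D2:**
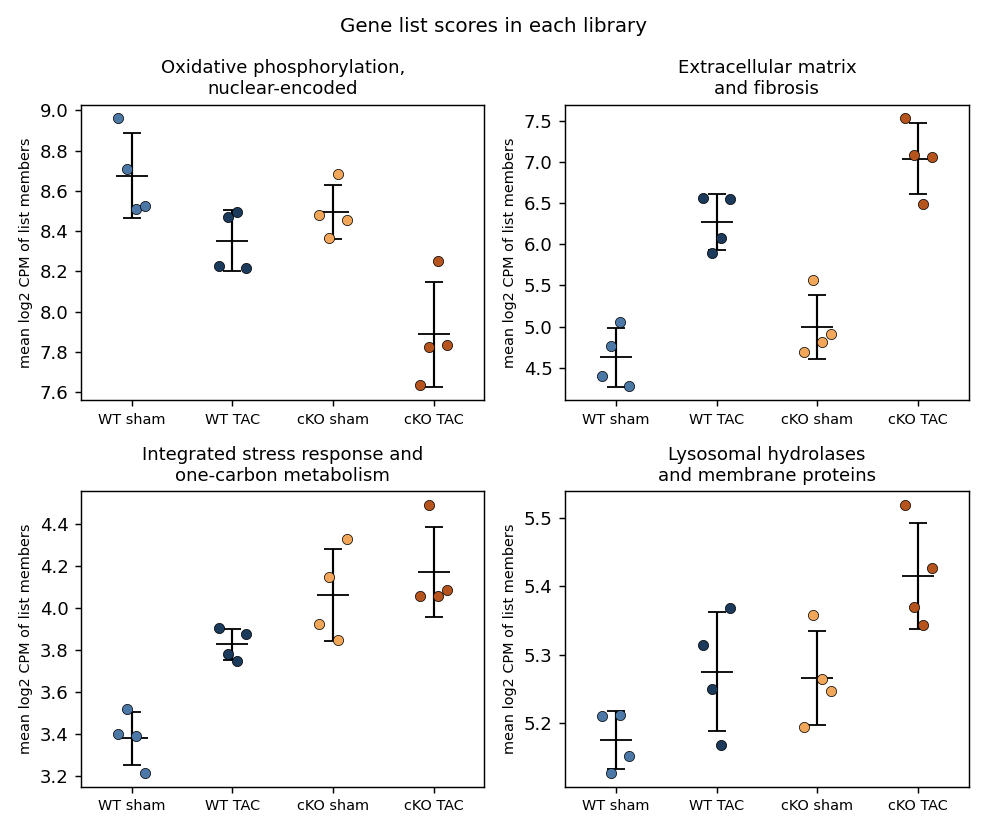
Mean log2 CPM of the members of 4 gene lists in each library; points are libraries, the horizontal bar is the group mean and the whiskers are 1 SD (n = 4). The oxidative phosphorylation score is 0.464 lower in cKO TAC than in WT TAC (exact p = 0.0857), with 1 cKO TAC library inside the WT TAC range.

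The differences between cKO and WT under sham and under TAC were set side by side. Both comparisons shared 23 genes that rose (0.563 if independent) and 26 that fell (0.994 if independent), with none called in opposite directions. Mthfd2, Tent5b and Kcnj14 rose in both, and Tfeb, Clcn1, Efnb3, Tmem150c and Immp2l fell in both. Without WT TAC replicate 2 the TAC calls of Mthfd2, Tent5b, Kcnj14, Tfeb and Efnb3 were lost, with adjusted p from 0.0645 to 0.113. Across all tested genes, which are not independent replicates, the fold changes had a Pearson r of 0.564. Uchl1, a ubiquitin hydrolase, rose 1.94-fold under sham and 1.83-fold under TAC, and Bckdhb fell to 0.618 and 0.624 of the WT level. With the 2 WT libraries rich in atrial transcripts left out, 27 of the 49 shared genes were still called in both comparisons, while the fold changes of the 49 stayed as large (median ratio 1.04 under sham and 1.01 under TAC).

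**Figure D3:**
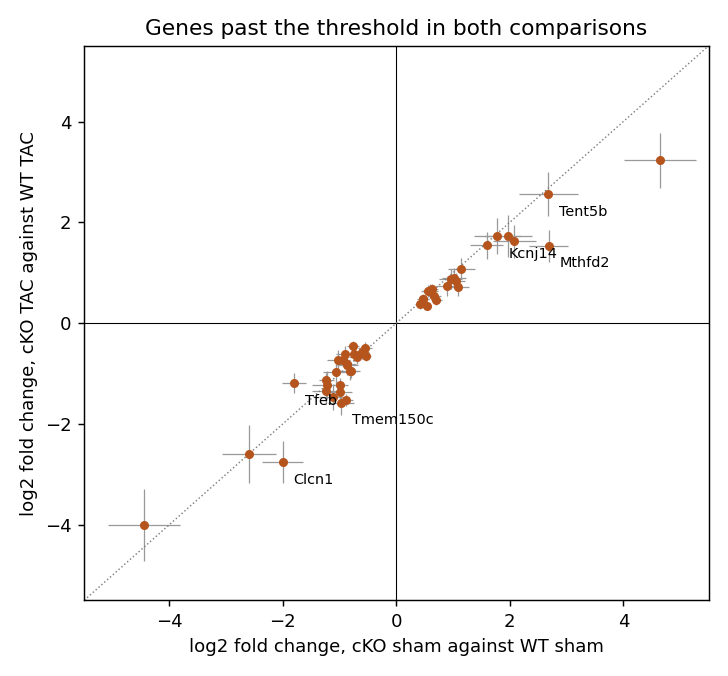
Log2 fold change of cKO against WT under sham (horizontal axis) and under TAC (vertical axis) for the 49 genes past the threshold in both comparisons; whiskers are 1 SE and the dotted line marks equal effects. All 49 genes changed in the same direction, 23 upward and 26 downward.

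The interaction asks whether the TAC response differs between genotypes. No gene passed in edgeR, where 715 genes had an unadjusted p under 0.05, and none passed in limma voom. The DESeq2 Wald test called 3, among them Socs3 and Cnksr1 (the last chosen after its values were seen). Cnksr1 gave a log2 interaction of -1.13 (SE 0.24, adjusted p = 0.801 in edgeR and 0.0457 in DESeq2). Socs3 gave -1.48 (SE 0.31, adjusted p = 0.801 in edgeR and 0.0337 in DESeq2). Nuclear-encoded oxidative phosphorylation genes had a median interaction of -0.27 with no gene past the threshold (none adjusted over the list alone; camera down, adjusted p = 5.13e-15, and adjusted p = 0.656 with an estimated correlation), and matrix genes one of 0.32 (none adjusted over the list alone; adjusted p = 0.744 with an estimated correlation). The lysosomal list gave 0.04 (none adjusted over the list alone; adjusted p = 0.262) and the autophagy list -0.02, or 0.04 with library totals only (none adjusted over the list alone; adjusted p = 0.620).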

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

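The tests of single libraries and of the interaction were fixed before the data were examined; the explanations weighed here and the splits of the libraries were tests chosen after the results were seen.

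A library far from the 3 others of its group was found in 19 of 680 groups tested (Dixon test), and chance flags about 1 in 20 groups, or 34 here. WT TAC replicate 1 held 4 of them: Atp2a2 at 8921 CPM (others 11090 to 11379), Lgals4 at 18.2 CPM (44.8 to 48.1), Sdhc at 306.3 CPM (380.2 to 390.5) and the interferon list score at 4.21 (3.79 to 3.86). In WT TAC replicate 4 the fibroblast list score was 6.37 (5.83 to 5.92). In WT sham replicate 3 Idh3g was at 482.3 CPM (548.4 to 562.9) and Bckdhb at 57.1 CPM (74.2 to 75.9). In WT sham replicate 1 Sprr1a was at 1.45 CPM (0.0739 to 0.0773), and the score of sex-linked transcripts was 4.70 (5.15 to 5.21). In cKO sham replicate 1 Igfbp2 was at 0 CPM (0.194 to 0.223). In cKO sham replicate 2 Loxl3 was at 12.2 CPM (8.02 to 8.51) and Isg15 at 4.98 CPM (3.52 to 3.67). In cKO TAC replicate 1 Perm1 was at 176.2 CPM (241.3 to 251.1), Actn2 at 1853 CPM (2062 to 2079) and the macrophage and monocyte score at 4.61 (4.16 to 4.23). In cKO TAC replicate 2 Mitf was at 23.1 CPM (26.7 to 27.4) and the stress response and one-carbon score at 4.49 (4.06 to 4.08). In cKO TAC replicate 3 mt-Nd2 was at 17960 CPM (12173 to 12983), and the share of mitochondrially encoded counts was 20.4% (16.1% to 16.3%).

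On the interaction camera called 13 lists. None of them passed with an estimated correlation (smallest adjusted p = 0.656), so a difference between genotypes in the TAC response is not shown. As many lists were called by 37 of 100 splits. These splits can carry the genotype difference itself into the interaction, so that share is no measure of chance. No gene passed in edgeR (715 at an unadjusted p under 0.05) or limma voom, and 3 passed in the DESeq2 Wald test. The median interaction was below 0 in nuclear-encoded (-0.27) and mitochondrially encoded (-0.22) oxidative phosphorylation, mitochondrial biogenesis (-0.12), fatty acid oxidation (-0.27), the citric acid cycle (-0.25), glycolysis (-0.10) and branched-chain amino acid and ketone catabolism (-0.18). It was also below 0 in hypertrophy markers (-0.16), contraction (-0.18), the stress response (-0.26), endoplasmic reticulum chaperones (-0.10) and the proteasome (-0.11), and above 0 in matrix genes (0.32).

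Whether counts as large arise by chance was asked by refitting other splits of the same libraries. For WT TAC against WT sham 1 of 35 splits, the real one, called as many as 2409 genes, and the highest other called 16. For cKO TAC against cKO sham it was again 1 of 35, with 4034 genes against 5, and for cKO sham against WT sham 1 of 35, with 178 against 17. Chance is argued against for these 3 counts and not excluded, since 1 of 35 is the smallest share this test can give. The other splits mix libraries of both groups, so the size of the gap to their counts is no measure of chance. For cKO TAC against WT TAC 2 of 35 splits reached 271, and the other, which exchanges WT TAC replicate 1 with cKO TAC replicate 3, called 586, so chance cannot be excluded. For the interaction the real count is 0, which all 100 drawn splits reach by construction, so they say nothing about chance there. The highest of them called 737, and the next highest 16. Each draw moves the genotype labels separately within sham and within TAC, so a genotype difference shared by both surgeries can enter the interaction. It entered in that draw, with WT TAC replicates 2, 3 and 4 and cKO TAC replicate 3 labelled cKO TAC. Labelled cKO sham were WT sham replicate 3 and cKO sham replicates 2, 3 and 4. That draw also parts the TAC libraries as the exchange above does, but 2 other draws that part them so called 0 genes. In these 2 the sham labels did not add to the TAC difference. Draws with all WT TAC libraries labelled cKO TAC and mostly cKO sham libraries labelled cKO sham also called 0. Neither feature alone thus accounts for the 737. By these splits chance cannot be excluded for any count of lists called by camera. As many were called by 6 of 35 splits in WT TAC against WT sham (21, highest other 24) and 6 of 35 in cKO TAC against cKO sham (19, 20). The same held for 6 of 35 in cKO sham against WT sham (15, 19), 14 of 35 in cKO TAC against WT TAC (15, 18) and 37 of 100 in the interaction (13, 20). In the first 3 comparisons each other split that did so kept 3 libraries of a group together, and with them part of the real difference. Splits with 2 libraries of each group on either side called at most 18, 15 and 14 lists there, and up to 18 in cKO TAC against WT TAC. The interaction draws can carry the genotype difference. These shares are thus no clean measure of chance.

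A first pattern is that the atrial transcripts Myl7, Sln and Myl4, chosen after their values were seen, were high in single WT libraries, with Myl7 at 868.7 CPM in WT sham replicate 3 and 344.8 CPM in WT TAC replicate 4. Atrial tissue in the ventricular sample is a candidate explanation: 9 of 14 other atrial markers were highest in WT sham replicate 3 (0.875 by chance). This stays short of the 3 in 4 asked of that test, so the source stays open. A rise by TAC is argued against by the sham libraries themselves, since Myl7 was at 84.7, 868.7 and 44.0 CPM in WT sham replicates 2, 3 and 4 and at 4.53 CPM or less in WT TAC replicates 1, 2 and 3. That 0 of the 8 TAC libraries lay above every sham library of their genotype adds nothing for WT, where WT sham replicate 3 set the outcome, and in cKO the levels were near 0.

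A second pattern is the lower score of nuclear-encoded oxidative phosphorylation in cKO TAC than in WT TAC (-0.46, exact p = 0.0857, n = 4). A lower share of cardiomyocyte RNA is argued against only weakly as the whole cause. The score was also lower relative to that of contraction genes (-0.30, exact p = 0.0286, the smallest possible). But the groups parted narrowly there, with cKO TAC replicate 3 at -1.97323 and WT TAC replicate 4 at -1.97175. A lower share stays open for a part, since contraction was itself lower (-0.16, exact p = 0.0857) and matrix higher (0.770, exact p = 0.0857). Scaling between libraries is argued against by the list median, which stayed at -0.36 or lower under 3 scalings. A spread of the TAC response between single hearts stays open, since the scores of the 2 groups overlap (exact p = 0.0857): exchanging WT TAC replicate 1 with cKO TAC replicate 3 gave a difference of -0.48, but that adds nothing, because the second (8.25) lies above the first (8.23), and an effect of TFEB loss stays open beside it.

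The last pattern is the set of 49 genes that differed between cKO and WT in the same direction under sham and TAC. Strain variants linked to the Tfeb locus are argued against as the whole cause by 0 of these genes among 398 tested neighbours of Tfeb (1.26 by chance). Gene length bias is argued against as the whole cause, since the trend on gene span made up at most 27.4% of the fold change of any of the 48 genes with a span (median 2.64%); that 0 of them fell below 2 standard errors without it adds little, as each was chosen for passing in both comparisons. Atrial tissue in WT libraries is argued against under TAC by a median ratio of 1.01 for the fold changes without the 2 libraries. Under sham the ratio was 1.04, but atrial tissue stays open there for a part. WT sham replicates 2 and 4 still held Myl7 at 84.7 and 44.0 CPM without TMM factors, against at most 3.29 in cKO sham. With atrial transcripts as a covariate 70 of all 178 sham calls and 269 of all 271 TAC calls were kept. An effect of TFEB loss stays open as a hypothesis found and tested on the same data, beside passenger variants elsewhere in the genome and Cre recombinase, which were not tested.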

How the results depend on the processing

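The alternatives were planned before the data were examined, except that leaving out the 2 libraries with atrial transcripts and using these transcripts as a covariate were tests chosen after seeing the data. No result changed its direction past the threshold. Of 13317 values of named genes 12528 stayed on their side of the threshold, 571 lost a call and 218 gained one; of 3120 values of single lists 2805 stayed, 213 lost and 102 gained. Counts of genes stayed within 1.5 times in 86 of 107 cases and counts of lists in 72 of 83. The share for genes pools unlike comparisons. It includes the interaction, where nearly all counts were 0, and cKO TAC against WT TAC, where the count ran from 13 to 912. Unless stated, the cause was not tested.

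The DESeq2 Wald test called 546 genes in cKO sham against WT sham, 823 in cKO TAC against WT TAC and 3 in the interaction. Without a low-count filter 438 genes passed in cKO TAC against WT TAC, and with only the compared groups 152, with fewer residual degrees of freedom; there Tfeb stayed at -1.19 without passing (adjusted p = 0.0543; over its alternatives up to 0.0645). With the 2 libraries with atrial transcripts left out 165 passed in cKO TAC against WT TAC and 2 in the interaction, and with atrial transcripts as a covariate 115 passed in cKO sham against WT sham and 686 in cKO TAC against WT TAC. The labels do not pair the replicates, and profiles with the same replicate number had a median correlation of 0.0206 after group means were removed. With replicate number as a block 2336, 3986, 235, 302 and 0 genes passed in the 5 comparisons.

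With an estimated correlation 0 lists passed in WT TAC against WT sham, in cKO TAC against cKO sham, in the 2 genotype comparisons and in the interaction. The directional test of fry called 18 lists in WT TAC against WT sham, 22 in cKO TAC against cKO sham, 1 in cKO sham against WT sham, 6 in cKO TAC against WT TAC and 0 in the interaction. Its mixed test called 32, 32, 17, 21 and 0 in the same order. At an adjusted p under 0.01 the TAC responses shared 565 higher and 168 lower genes, and the differences between cKO and WT 1 and 6. At a minimum of 10 counts in place of 1 the difference in genes detected between cKO sham and WT sham was 138.5 in place of 705.75.

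Leaving out 1 library at a time gave 1234 genes (without WT TAC replicate 1) to 2456 (without WT sham replicate 3) in WT TAC against WT sham and 2720 to 4297 in cKO TAC against cKO sham. It gave 59 (without cKO sham replicate 4) to 211 (without WT sham replicate 2) in cKO sham against WT sham, and 13 (without WT TAC replicate 2) to 912 (without cKO TAC replicate 3) in cKO TAC against WT TAC. Tfeb under TAC ranged from -1.33 (without WT TAC replicate 4) to -1.0004 (without WT TAC replicate 1) and under sham from -1.92 to -1.74. Thinned to the shallowest total, 2377, 3936, 187, 278 and 0 genes passed in the 5 comparisons, close to the counts at full depth. In simulated data with 4 libraries per group 31.3% of genes changed 1.5-fold were recovered in cKO sham against WT sham and 16.4% in the interaction.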

Other observations

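The tests of lists were fixed before the data were examined; the test of very long genes was chosen after the result was seen.

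Further lists were tested. Of 29 cell death and cyclin-dependent kinase inhibitor genes 11 rose and 1 fell with TAC in WT (12 and 1 adjusted over the list alone; adjusted p = 0.000297, and adjusted p = 0.194 with an estimated correlation). In cKO sham against WT sham 2 of them rose (5 adjusted over the list alone; adjusted p = 0.0202, and adjusted p = 0.527 with an estimated correlation), where the median was -0.01 but the mean 0.19 and the test upward. Endothelial markers rose in 6 of 25 cases with TAC in WT (7 adjusted over the list alone; adjusted p = 0.465 with an estimated correlation) and endoplasmic reticulum chaperones in 4 of 24 (4 adjusted over the list alone; adjusted p = 0.465 with an estimated correlation). With TAC in cKO 7 of 37 proteasome and cytosolic chaperone genes fell (6 adjusted over the list alone; median -0.13, or 0.06 with library totals only; adjusted p = 0.473 with an estimated correlation). Immediate early and tissue handling genes rose in 5 of 26 cases in the same comparison (5 adjusted over the list alone; adjusted p = 0.510 with an estimated correlation). In cKO sham against WT sham the same list was lower by camera (median -0.35, adjusted p = 0.0485, and adjusted p = 0.699 with an estimated correlation), although 2 of its genes rose and none fell over all genes (2 rose and 6 fell adjusted over the list alone).

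The following 12 lists did not pass by camera with TAC in WT. Of 18 smooth muscle and pericyte markers 5 rose and 1 fell (5 and 2 adjusted over the list alone; adjusted p = 0.124), of 8 lymphocyte markers 1 rose (1; 0.183), of 4 neutrophil and mast cell markers 1 rose (2; 0.153) and of 4 epicardial and mesothelial markers 1 rose (2; 0.233). Of 8 adipocyte markers 1 fell (1 rose and 1 fell; 0.996), and of 10 Schwann cell and neuronal markers 1 rose and 1 fell (1 and 1; 0.144). Of 35 antioxidant and NRF2 targets 1 rose and 5 fell (1 and 5; median -0.12, or 0.00 with library totals only; 0.153), of 28 cholesterol and lipid synthesis genes 1 rose and 2 fell (1 and 2; median -0.07, or 0.05 with library totals only; 0.661), and of 25 hypoxia and angiogenesis genes 2 rose and 2 fell (2 and 2; 0.661). Of 19 circadian clock genes 1 rose (0; 0.866), where the median was 0.02 and the mean -0.03, and of 44 cytosolic ribosomal protein genes 1 rose (1; median -0.08, or 0.06 with library totals only; 0.484). Of 4 sex-linked transcripts none passed (0; 0.183).

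Ddx3y, a gene of the Y chromosome, held 833 to 1292 counts in each of the 16 libraries, and Xist, expressed from an inactive X chromosome, 0 to 5 counts. Nnt, of which the C57BL/6J substrain is known to carry a partial deletion, held 12 to 57 counts (0.822 to 3.55 CPM without TMM factors) in each of the 16 libraries, and the labels give the strain as C57/BL6N.

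A hypothesis from these data was that genes with a span over 1 Mb are lower after TFEB loss. The mean of 30 such genes relative to all genes differed by -0.22 in sham (exact p = 0.0857) and by -0.16 in TAC (exact p = 0.0286, the smallest possible, n = 4). The test asked for an exact p under 0.05 in both surgeries, so it was negative.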
